A study of Brassica napus with 6 samples.

How the data were processed

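RNA sequencing of HZ62, a hybrid of oilseed rape (Brassica napus), covered 3 tissues with 2 libraries each: seedling, flower bud and silique. Per the labels' protocols, libraries were made from polyadenylated RNA with a TruSeq RNA kit. HISAT2, SAMtools, GATK, featureCounts and edgeR are named in the submitters' processing notes, and the versions, settings and role of each tool are not given in the sources used here. The genome build is likewise not given in the sources used here, so positions below are those of the gene models in the count table, counted from 1. Gene identifiers in that table begin with ZS11 and its sequences are named with a GWHANRE prefix. Whether counting used the strand of the reads is also not given in the sources used here, and genes that overlap another gene model were treated as uncertain.

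Per the file headers, the deposited count table holds whole-number counts of reads per gene with the columns that featureCounts writes. It listed 65535 genes, a number equal to the row limit of an older workbook sheet below its header, and it ended inside chromosome C3 at 63856963 bp. Of these genes, 44373 lay on A chromosomes, 20545 on C chromosomes and 617 on unplaced sequences, so 13 of 19 chromosomes were reached. The stated length of a gene equalled its end minus its start plus 1 in 100% of genes, which is the span of the gene with any introns. Exons and untranslated regions are therefore not told apart here.

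The deposited normalized table holds a signal per gene that the authors scaled with trimmed mean of M values (TMM) factors, per the name of the deposited file. It listed 80932 genes on 19 chromosomes, of which 51324 were also in the count table. The values in each library were whole multiples of 1 step, so whole reads were recovered by dividing by that step. In each library 100% of values came out whole within a tolerance of 0.05 reads, and 100% of the genes shared with the count table gave the same count. The 29608 genes found only in the normalized table could thus be counted in reads. The 14211 genes found only in the count table had 0 reads, and 7676 genes of the normalized table had no read. Recovered reads were used for library depth, for shares of reads by chromosome and subgenome, and as an alternative count test chosen after the data were examined. Reads on unplaced sequences were 0.107% of the recovered reads. The count table held between 63.9% and 64.6% of the recovered reads of a library.

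Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr with its minimum count of 10, and the quasi-likelihood F test (glmQLFit and glmQLFTest). All 6 libraries entered 1 fit without a replicate block, which left 3 residual degrees of freedom. The common biological coefficient of variation was 0.162. Of the listed genes, 34296 passed the filter. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Genes were called highest (or lowest) in a tissue when they were called higher (or lower) there than in both other tissues. Counts-per-million values (CPM) were computed relative to the reads of the count table after TMM scaling, not to the whole library. Where a tissue had 0 reads of a gene, the fold was computed against 3 counts over both of its libraries and is written as a lower bound. Such bounds, and all intervals of shares (Wilson, 95%), cover counting error only, since reads without molecular identifiers are not independent molecules. Nothing in the labels says that the 2 libraries of a tissue came from separate plants, so p-values measure the spread between these samples, which may be technical. Each gene had 1 dispersion shared by the 3 tissues. P-values between silique and flower bud therefore also carry the spread between the seedling libraries.

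Gene names could not be assigned. The files do not pair identifiers with names, and 0 of 95143 identifiers matched the table of named genes used as a reference, which describes the Da-Ae assembly. The 20 gene lists fixed before the data were examined, with their set tests, were therefore not run. Under the rule fixed for that case, 2 identifiers that rose and 2 that fell are named per pair of tissues. They are those with the largest fitted changes among called genes with a mean of at least 50 CPM in the higher tissue and no overlap between the libraries of the pair.

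Shares of reads from the A and C chromosomes were compared with a two-sided exact permutation test. Shares of called genes were compared with two-sided Fisher exact tests and Benjamini-Hochberg adjustment. Tests by chromosome, runs of neighbouring genes and windows of 50 genes moved in steps of 10 genes were added after the data were examined. In the windows, a gene was counted as expressed at a total of at least 60 reads over the 6 libraries, and low windows held at most 6 expressed genes. Python 3.11.15, SciPy 1.17.1, pandas 2.3.3 and NumPy 2.4.6 were used for these steps.

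The count test was tested on simulated data drawn from the means and library sizes of the real libraries, with 100 genes changed 4-fold and 100 changed 8-fold. For flower bud against seedling it recovered 71% of the 4-fold and 91% of the 8-fold changes among 33250 genes, with 16 false calls. For silique against seedling these were 76% and 90% among 33266 genes, with 17 false calls. For silique against flower bud they were 80% and 89% among 33227 genes, with 27 false calls. In each pair, false calls were a larger part of the simulated calls than the adjusted p threshold of 0.05 allows on average. Only 200 genes were changed, whereas between 27.5% and 43.0% of the tested genes were called in the data. Recovery, false calls and TMM scaling under such wide change were not tested. Alternatives fixed before the data were examined were other size factors, DESeq2 1.42.0, limma 3.58.1 on the normalized values, other filters, a replicate block, a fit of each pair alone, other thresholds and leaving out each library. Added later were the recovered reads of all chromosomes, library totals of all recovered reads, and thinning of every library to 2538852 reads.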

Results

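Gene expression was profiled by RNA sequencing in HZ62, a hybrid of oilseed rape (Brassica napus). This species is an allotetraploid that carries an A subgenome, related to that of Brassica rapa, and a C subgenome, related to that of Brassica oleracea. Seedlings of 2 weeks, flower buds shorter than 2 mm and siliques (the pods that hold the seeds) of 3 to 5 cm were sampled from plants grown under 16 h of light at 22 °C and 8 h of dark at 18 °C, with 2 libraries per tissue. The series also concerns the parents of the hybrid, which were not analysed here.

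Seedling replicate 1 was the deepest library with 24110359 recovered reads, and seedling replicate 2 the shallowest with 3973408. Flower bud libraries held 12614212 and 12543622 reads, and silique libraries 12506762 and 10359099. In the count table, where the tests were run, the totals ranged from 2538852 in seedling replicate 2 to 15448095 in seedling replicate 1. Despite the difference in depth, the number of genes with a normalized value of at least 1 lay between 43733 and 46127 in all 6 libraries, and 35777 genes reached that value in every library. The 10 most abundant genes took 2.32% of the reads in seedling replicate 1 (Wilson 95% interval 2.318 to 2.33) and 4.63% in seedling replicate 2 (4.61 to 4.65). Their share was 0.836% (0.831 to 0.841) and 0.803% (0.798 to 0.808) in flower bud, and 1.605% (1.598 to 1.61) and 1.58% (1.57 to 1.59) in silique.

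Libraries of 1 tissue resembled each other more than those of other tissues. Across genes, the Pearson correlation of log2 CPM was 0.929 between the seedling libraries, 0.981 between the flower bud libraries and 0.976 between the silique libraries, and it ranged from 0.583 to 0.744 between tissues. The first principal component held 57.1% of the variance and set seedling, silique and flower bud apart in that order. The second held 34.1% and set silique apart from both other tissues. Replicate counts differed by more than sampling noise in every tissue, with a chi-square per gene of 15.2 in seedling, 2.51 in flower bud and 2.41 in silique, so no library was counted as a second sequencing of another. This does not tell separate plants from separate preparations of 1 RNA.

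Flower buds and seedlings differed most in the number of genes called. Of 34296 genes tested, 7250 were higher and 7484 lower in flower bud, together 43.0% of the genes. The changes were large: the median log2 fold change was 1.87 among the higher genes and -2.37 among the lower genes, or 1.85 and -2.34 with genes at 0 reads set to their bound. At least an 8-fold difference was reached by 1932 of the higher and 2611 of the lower genes. Of the called genes, 934 had no read in seedling and 492 had no read in flower bud.

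In flower bud, ZS11A04G005680 (chromosome A4, 4184009 to 4185983, minus strand) stood at 1046.6 ± 5.15 CPM (SD, n = 2) and had 0 reads in seedling. This was at least 5648-fold higher (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.42e-07), and the gene was at 0.12 CPM in silique, from 2 reads in 1 library. ZS11A03G013860 (chromosome A3, 6849041 to 6849858, minus strand) stood at 808 ± 51.4 CPM in flower bud with 0 reads in seedling, at least 4361-fold higher (edgeR adjusted p = 4.49e-07). Of the genes that fell, ZS11A07G023900 (chromosome A7, 19674762 to 19678071, plus strand) had 942 ± 599 CPM in seedling and 0 reads in flower bud (edgeR adjusted p = 2.46e-06). Its seedling libraries lay far apart, at 518 CPM in replicate 1 and 1366 CPM in replicate 2, so it was at least 3186-fold lower from replicate 1 alone and at least 5790-fold lower from the mean. ZS11A01G036600 (chromosome A1, 27923109 to 27924505, plus strand) had 493 ± 112 CPM in seedling and 0 reads in flower bud, at least 3032-fold lower (edgeR adjusted p = 6.26e-07). None of these 4 genes overlapped another gene model. The median log2 fold change of all tested genes was 0.12 with TMM, 0.08 with relative log expression factors and 0.17 with upper quartile factors. The balance of higher and lower genes is relative to that shift. The authors' own scaling set flower bud and silique higher relative to seedling than the TMM factors used here. Its median shift was not computed. Limma on the normalized values used that scaling and another test, and the effects of the 2 were not told apart. The balance turned to 10422 higher and 4965 lower with limma on the normalized values, 8487 and 6839 without seedling replicate 1, 7672 and 7254 with upper quartile factors, and 10028 and 9233 by adjusted p alone, while glmTreat gave 4137 higher and 5453 lower genes, and with the recovered reads of all chromosomes 10923 were higher and 11372 lower among 52918 genes tested.

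Siliques also differed widely from seedlings. In silique 5573 genes were higher and 6164 lower, together 34.2% of those tested. The median log2 fold change was 1.85 among the higher genes and -2.13 among the lower genes, or 1.82 and -2.10 with genes at 0 reads set to their bound. At least an 8-fold difference was reached by 1576 of the higher and 1757 of the lower genes. In seedling 832 of the called genes had no read, and in silique 391 had none.

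ZS11A01G007130 (chromosome A1, 3733326 to 3734999, plus strand) stood at 625 ± 43.2 CPM in silique (SD, n = 2) and had 0 reads in the other 4 libraries, at least 3374-fold higher than in seedling (edgeR adjusted p = 8.34e-07). It overlaps 1 other gene model, so its level is uncertain. ZS11A01G037110 (chromosome A1, 28257674 to 28260070, minus strand) had 531 ± 18.7 CPM in silique, 127 ± 1.86 CPM in flower bud and 0 reads in seedling, at least 2863-fold higher in silique than in seedling (edgeR adjusted p = 3.01e-07). Both genes named as lower in silique lie close to each other on chromosome A1. ZS11A01G036600, which had 0 reads in flower bud, also had 0 reads in silique, at least 2508-fold lower than in seedling (edgeR adjusted p = 1.22e-06). ZS11A01G036620 (27950030 to 27951432, plus strand) had 240.2 ± 13.8 CPM in seedling and 0 reads in silique, at least 1221-fold lower (edgeR adjusted p = 7.27e-07). The balance turned to 7431 higher and 4022 lower with limma on the normalized values and to 7190 and 5681 without seedling replicate 1, and glmTreat gave 2982 and 3810. The recovered reads of all chromosomes gave 8418 higher and 9381 lower genes.

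The 2 reproductive tissues differed least in the number of genes called. Compared with flower bud, 4966 genes were higher and 4450 lower in silique, together 27.5% of those tested. The called changes were as large as in the other pairs, with a median log2 fold change of 2.16 among the higher genes and -2.32 among the lower genes, or 2.11 and -2.29 with genes at 0 reads set to their bound. At least an 8-fold difference was reached by 1607 of the higher and 1607 of the lower genes. In flower bud 767 of the called genes had no read, and in silique 817 had none.

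ZS11A01G007130 was at least 3843-fold higher in silique than in flower bud (edgeR adjusted p = 6.4e-07). ZS11A03G047750 (chromosome A3, 25482845 to 25486257, plus strand) had 312 ± 13.8 CPM in silique (SD, n = 2), 0.50 ± 0.71 CPM in seedling and 0 reads in flower bud, at least 1920-fold higher in silique (edgeR adjusted p = 1.36e-06). ZS11A03G013860 was at least 4108-fold lower in silique than in flower bud (edgeR adjusted p = 6.71e-07), with 0 reads in silique as in seedling. ZS11A10G027760 (chromosome A10, 20193938 to 20194817, plus strand) had 796 ± 67.1 CPM in flower bud and 0 reads in both other tissues, at least 4045-fold lower in silique (edgeR adjusted p = 6.87e-07). The count of lower genes fell to 2736 without flower bud replicate 1, 2670 without flower bud replicate 2, 2686 without silique replicate 1 and 2850 without silique replicate 2. With limma on the normalized values the balance turned to 3635 higher and 4085 lower, and with glmTreat 2944 genes were higher and 2558 lower. The recovered reads of all chromosomes gave 7485 higher and 6579 lower. The shared fit includes the seedling libraries, which agreed least with each other. A fit of each pair alone gave 5188 higher and 4957 lower genes here, against 4919 and 5842 in silique against seedling. The 2 pairs thus lay closer than in the shared fit.

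**Figure D1:**
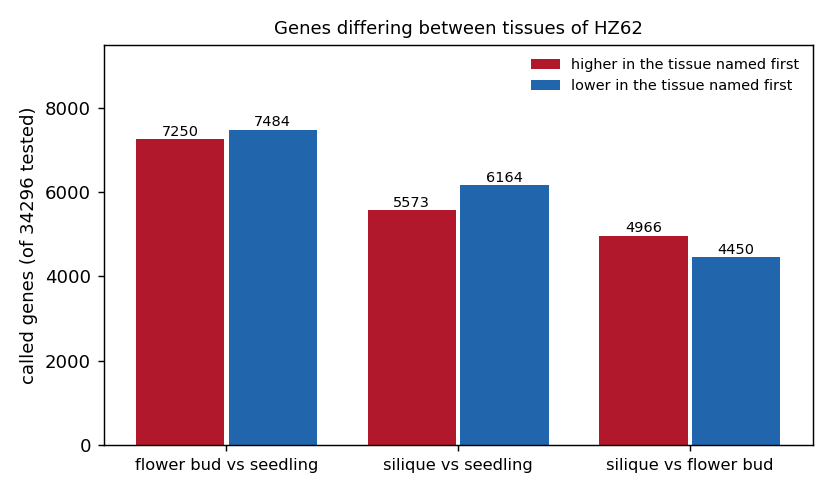
Number of genes called higher (red) and lower (blue) in the tissue named first, for each pair of tissues, out of 34296 genes tested with 2 libraries per tissue. Flower bud against seedling has the tallest bars (7250 and 7484) and silique against flower bud the shortest (4966 and 4450).

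In seedling 4583 genes were higher than in both other tissues, against 2861 in flower bud and 1919 in silique. The order of seedling and flower bud depended on the test, since limma on the normalized values gave 3028 genes for seedling and 3062 for flower bud. Genes lowest in 1 tissue numbered 3136 in seedling, 2790 in flower bud and 1229 in silique. The order of seedling and flower bud turned with glmTreat (1260 and 1367) and without seedling replicate 2. Limma on the normalized values set them far apart, with 4745 in seedling and 1481 in flower bud, and gave 601 in silique. Expression in a single tissue was less common: of all genes of the normalized table, which covers 19 chromosomes, 659 had a normalized value of at least 1 in both flower bud libraries and no read in the other 4 libraries, as did 577 for silique and 152 for seedling. The last count rests on the shallowest library, seedling replicate 2, and is not compared with the others. Of all genes tested, 14927 (43.5%) were called in none of the pairs. Independent lists of these sizes would share 1345 genes highest in seedling, 941 in flower bud and 807 in silique. As the 2 comparisons behind each class share libraries, part of the excess over these numbers may come from the shared libraries. The 20 simulations without any difference gave at most 1 gene in any class. They made only 4.5 calls on average, so they cannot show what shared libraries add when many genes differ. Genes highest in flower bud fell to 1735 and 1673 without flower bud replicate 1 or 2 and to 1829 without silique replicate 1, and genes lowest in seedling rose to 4898 without seedling replicate 1. Genes lowest in silique fell to 765 and 755 without flower bud replicate 1 or 2 and to 667 and 713 without silique replicate 1 or 2.

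Genes highest in the same tissue also lay side by side. Runs of at least 5 consecutive tested genes numbered 9 for seedling, 1 for flower bud and 1 for silique. As more genes were highest in seedling, more runs would be met there, and no expected number of runs was computed. Against genes shuffled within chromosomes, adjacent pairs were 1.93 times as many for silique, 1.39 for seedling and 1.33 for flower bud. The longest run held 11 genes highest in seedling, all on the same strand, on chromosome C1 between 50941520 and 51221206, a stretch with 28 gene models. Together these 11 genes had 1167 ± 33.2 CPM in seedling, 36.4 ± 3.08 in flower bud and 45.2 ± 9.35 in silique (SD, n = 2), and single genes ranged from 3.06 to 304 CPM in seedling. On chromosome A3, between 13873300 and 13983786, a run of 6 genes had 1247 ± 381 CPM in seedling, 187 ± 9.77 in flower bud and 397 ± 6.04 in silique, and 1 gene gave 905 of the 1247 CPM. The silique run lay on chromosome A5 between 28409212 and 28428841, where 6 genes on the same strand had 93.8 ± 0.963 CPM in silique, 21.9 ± 1.69 in seedling and 14.97 ± 1.01 in flower bud. The flower bud run lay on chromosome A2 between 25093820 and 25235320, where 5 genes on the same strand had 29.8 ± 4.35 CPM in flower bud and 0 reads in the other tissues. The runs were looked for after the data were examined, and copies that share reads would be uncertain in level.

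**Figure D2:**
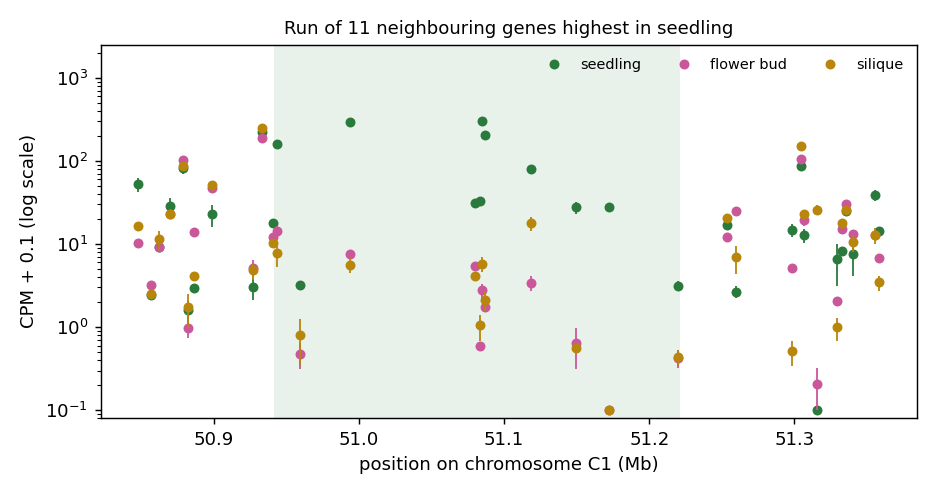
Mean CPM plus 0.1 (log axis) of each tested gene against its position in Mb on chromosome C1, in seedling (green), flower bud (pink) and silique (ochre). Bars span the range of the 2 libraries of a tissue. In the shaded stretch each of the 11 genes lies higher in seedling than in flower bud and silique, while genes on both sides show no single order.

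The A subgenome gave less than the C subgenome in total reads but more in mean reads per listed gene in each tissue. The normalized table listed 36011 A genes and 44636 C genes, so A genes were 44.7% of them. It leaves out some genes without reads, since the count table listed 44373 A genes, but it keeps others, as 7676 of its genes had no read. The count table stops inside C3, so the full number of C genes is not known. How evenly the 2 subgenomes lost genes was not tested over all chromosomes, and values per listed gene depend on it. On C1 the count table held 3058 genes before 23105439 bp and 3047 from there on, while 4386 were listed. On C2 it held 6491 genes beyond the first 316, while 4754 were listed on the whole chromosome. Both lost a larger part of their genes than the A chromosomes, which raises their reads per listed gene. C3 to C9 were not compared. Reads per listed gene were 1.11 ± 0.0113 times as many in A as in C in seedling, 1.106 ± 0.00394 times in flower bud and 1.15 ± 0.000665 times in silique (SD, n = 2). The A share of the reads on A and C chromosomes was 47.2% ± 0.255 in seedling, 47.2% ± 0.0887 in flower bud and 48.0% ± 0.0145 in silique (SD, n = 2). In seedling, counting error was small beside this spread, as the shares of 47.07% (Wilson 95% interval 47.05 to 47.09) in seedling replicate 1 and 47.43% (47.38 to 47.48) in replicate 2 show. The silique share was higher than the seedling share by 0.779 and than the flower bud share by 0.862 percentage points, which exceeded the spread between replicates. An exact permutation test with 2 libraries against 2 cannot go below p = 0.333, the value it gave for both. Flower bud and seedling differed by -0.083 points, less than the spread between seedling replicates (exact permutation p = 1.0). A larger part of the A genes than of the C genes listed in the normalized table had a normalized value of at least 1 in both libraries, 53.4% against 49.0% in seedling, 58.2% against 52.4% in flower bud and 56.9% against 50.8% in silique. The median normalized value of these expressed genes differed little, with 8.87 in A and 8.78 in C in seedling, 10.87 and 10.95 in flower bud, and 10.35 and 10.25 in silique.

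**Figure D3:**
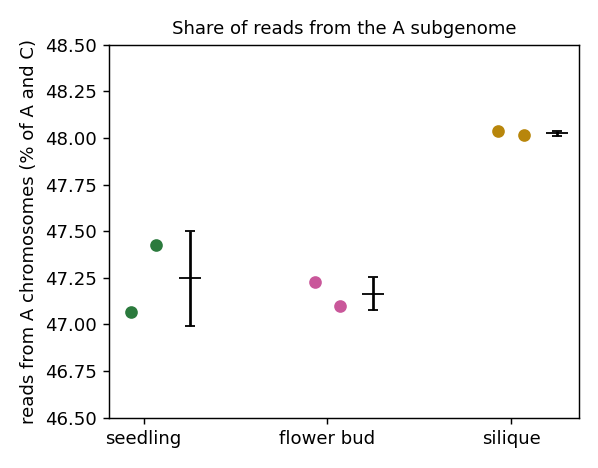
Share of reads from A chromosomes, in percent of reads on A and C chromosomes, for each library (points) with the mean and SD of each tissue (n = 2) beside them. The axis does not start at 0. Both silique libraries lie at 48.0%, above the 4 other libraries, which lie between 47.07% and 47.43%.

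Genes of the A subgenome were called more often than those of the C subgenome in each pair of tissues. With recovered reads, 43.6% of A genes and 40.8% of C genes differed between flower bud and seedling (two-sided Fisher exact test, Benjamini-Hochberg adjusted p = 5.27e-10), 34.7% and 32.7% between silique and seedling (adjusted Fisher exact p = 5.6e-06), and 27.7% and 25.6% between silique and flower bud (adjusted Fisher exact p = 2.54e-07). Among the genes called between silique and seedling, 49.96% of A genes but 44.7% of C genes were higher in silique, a difference that was not tested. Genes are not independent, so these p-values are too small. With the deposited counts, which hold only part of the C subgenome, the last comparison gave 27.7% and 26.7% (adjusted Fisher exact p = 0.0549) and no longer passed.

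Some chromosomes held more or fewer genes of a tissue than the rest. Genes highest in silique made up 7.07% of the tested genes of chromosome A2 against 5.35% elsewhere (adjusted Fisher exact p = 0.013), 7.13% of A7 against 5.35% (adjusted Fisher exact p = 0.013) and 6.62% of A3 against 5.34% (adjusted Fisher exact p = 0.0225). They were fewer on C5, with 4.18% against 5.50% (adjusted Fisher exact p = 0.0239), and on C3, with 4.499% against 5.51% (adjusted Fisher exact p = 0.0361). Genes highest in seedling were more frequent on C2, with 15.1% against 13.05% (adjusted Fisher exact p = 0.0304), and genes highest in flower bud less frequent on C8, with 6.69% against 8.09% (adjusted Fisher exact p = 0.0471). The other tests among the 57, which were run on recovered reads, did not pass, and neighbouring genes are not independent. For silique, the chromosomes with more such genes were all A and those with fewer all C. As the rest pooled both subgenomes, a difference between subgenomes is not told apart from differences of single chromosomes.

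Stretches with few expressed genes lay on several chromosomes. Of 64918 placed genes in the count table, 32348 (49.8%) had at least 60 reads over all libraries, and the median window of 50 genes held 26 of them. At most 6 expressed genes were found in 54 of 6433 windows, which merged into 18 regions. The lowest share was on chromosome A1 between 20243051 and 20950628, with 5 of 60 genes expressed, followed by A1 between 16860450 and 19413240 with 8 of 90 and A6 between 13919509 and 15936659 with 9 of 100. Those 3 regions were sparse in genes, with 84.8, 35.3 and 49.6 genes per Mb against 152 in the median window. On chromosome C2 the regions from 827504 to 1673666 (14 of 120 genes expressed) and from 1816840 to 2249785 (10 of 80) held 142 and 185 genes per Mb. Genes were as dense in a region of C2 from 47716241 to 48257098 (11 of 90 expressed, 166 genes per Mb) and in one of C1 from 20919574 to 21241042 (6 of 50, 156 genes per Mb). In 200 shuffles of genes within chromosomes, at most 2 windows of a shuffle were as low.

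**Figure D4:**
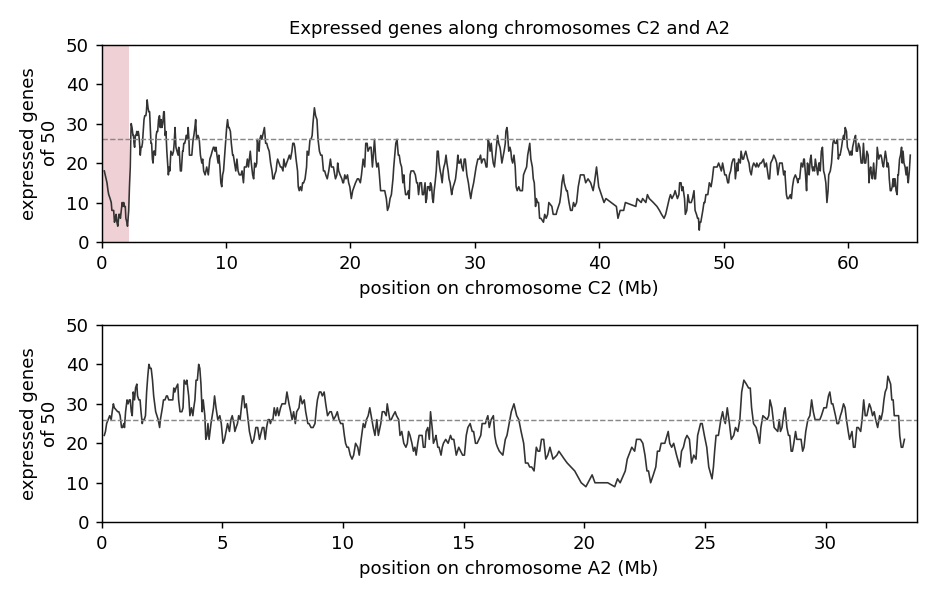
Number of expressed genes among 50 neighbouring genes (at least 60 reads over the 6 libraries) along chromosomes C2 (top) and A2 (bottom), by position in Mb. The dashed line marks the median of all windows (26), and the shaded start of C2, up to 2229791 bp, lies below the stretch that follows it. The end of the shaded part was placed where its contrast with the rest of C2 was largest.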

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

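The recovered reads, their library totals and the thinned libraries were chosen as alternatives only after the results were seen; the other alternatives were planned. All 228 values of named genes under the alternatives run kept their direction and their call. These genes were picked for the largest changes and had 0 reads in the lower tissue of the pair. Their stability was thus largely set by that choice and does not carry over to other genes. Of 234 counts and shares under alternatives, 195 stayed within 1.5 times the reported count or 1 SD of the reported share, and the 39 others follow; where a setting does not itself change the threshold, the genes tested or the libraries, the cause was not tested. The gene list tests, with estimated correlation included, were not run for lack of gene names, and a fit of each pair alone gives no genes highest or lowest in 1 tissue. Where leaving out a replicate left 1 library in a tissue, that library is assumed to vary like the others.

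The balance of higher and lower genes turned in all 3 pairs with limma, between flower bud and seedling also with upper quartile factors, with adjusted p alone and without seedling replicate 1 (8487 and 6839), and between silique and seedling also without seedling replicate 1 (7190 and 5681). Limma on the normalized values called 4965 genes lower in flower bud than in seedling and 4022 lower in silique than in seedling, with 3028 highest in seedling and 3062 in flower bud, which turned their order, 1481 lowest in flower bud, 4745 lowest in seedling and 601 lowest in silique. Limma here changed the scaling along with the test, and the effects of the 2 were not told apart. Adjusted p alone, a looser threshold, gave 4972 lowest in seedling. The stricter glmTreat gave 4137 higher in flower bud than in seedling, 2982 higher and 3810 lower in silique than in seedling, and 2944 higher and 2558 lower in silique than in flower bud. With it 5453 genes were lower in flower bud than in seedling, within 1.5 times the reported count. It gave 1693, 2865 and 1257 genes highest and 1367, 1260 and 524 lowest in flower bud, seedling and silique, which turned the order of genes lowest in seedling and flower bud, as did leaving out seedling replicate 2 (2854 and 3142). Recovered reads of all chromosomes, with more genes tested, gave 10923 higher and 11372 lower in flower bud than in seedling, 8418 and 9381 in silique against seedling, 7485 higher in silique than in flower bud, 6956 highest in seedling and 4204 lowest in flower bud. Thinned libraries, with fewer genes tested, gave 760 lowest in silique. Without the 10 most abundant genes the A share in silique was 48.1%, more than 1 SD from the reported value and on the same side of the other tissues.

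Without 1 library at a time, genes lower in silique than in flower bud ranged from 2670 to 5290, genes highest in flower bud from 1673 to 3200, genes lowest in seedling from 2342 to 4898 and genes lowest in silique from 667 to 1512.

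The replicate numbers are not said to pair libraries, and the differences between replicates 1 and 2 correlated at -0.017, 0.004 and -0.027 between tissues. With a replicate block the counts were 6953 higher and 7135 lower in flower bud than in seedling, 5336 and 5750 in silique against seedling, 4647 and 4055 in silique against flower bud, 2579, 4300 and 1774 highest and 2579, 2983 and 1042 lowest in flower bud, seedling and silique. The shallow second seedling library limits the smallest level detectable there, as 3 reads in it equal 1.51 CPM against 0.211 CPM in the first.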

Other observations

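The segment scan, the tests of gene density, shuffling and gene length at the start of chromosome C2, and the choice of that segment came only after the result was seen; the other tests were set before their values were seen. On chromosome A10, between 9997557 and 10103708, 5 neighbouring genes on the same strand had 38.04 ± 2.30 CPM in seedling, 0.814 ± 0.235 in flower bud and 1.28 ± 0.452 in silique (SD, n = 2). On chromosome A5, between 29380774 and 29426779, 6 genes had 736 ± 189 CPM in seedling, 583 of it from 1 gene, 143 ± 7.91 in flower bud and 288 ± 2.84 in silique. On chromosome A6, between 26038946 and 26094235, 5 genes had 135 ± 21.2 CPM in seedling, 7.48 ± 0.262 in flower bud and 25.3 ± 2.52 in silique. On chromosome A2, between 27550501 and 27599184, 5 genes had 247 ± 12.1 CPM in seedling, 33.7 ± 2.101 in flower bud and 66.8 ± 1.69 in silique. The seedling libraries lay far apart in the last 3 runs of 5 genes. On chromosome A3 (13320237 to 13357268) the sum was 870 ± 425 CPM in seedling, 678 of it from 1 gene, 124 ± 3.25 in flower bud and 292 ± 2.90 in silique. On A4 (17780608 to 17818199) it was 332 ± 214 CPM in seedling, 274 of it from 1 gene, 38.2 ± 4.52 in flower bud and 122 ± 11.1 in silique. On A9 (9455990 to 9549529) it was 668 ± 375 CPM in seedling, 475 of it from 1 gene, 94.7 ± 11.9 in flower bud and 150 ± 8.26 in silique.

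At the start of chromosome C2, from 9210 to 2229791, 56 of 316 genes were expressed (17.7%, Wilson 95% interval 13.9 to 22.3). Of the other C2 genes 37.9% were expressed, and of the next 50 genes 29. The scan placed the end of the segment where its contrast with the rest of C2 was largest. The low share and the higher share just past it are therefore partly set by that choice, which the interval does not cover. Against sparse genes stand 142.3 genes per Mb (103 in the rest of C2, 152 in the median window). Against short gene models stands a median gene length of 1971.5 bp, with 1702 bp in the rest of C2. Genes of the same lengths elsewhere were expressed at 50.1%, but these were pooled over all chromosomes, and the rest of C2 was itself at 37.9%. Against random grouping stands a log-likelihood ratio of 29.4, above the highest of 200 shuffles (11.1), which were scanned in the same way. An earlier form of the shuffle test asked that no shuffled window be as low as any gene-dense low window. This was not met, since those held 3 to 6 expressed genes and the lowest shuffled window 5. Higher ratios than at C2 came from segments at 1 end of A3, A7, A10, C1 and A1. The same held for one of C3 up to where the count table stops, and A3 gave 112, with 53.3 genes per Mb. Segments of A8 (26.2) and A2 (18.8) lay below that of C2 but also above every shuffle. A ratio above every shuffle was thus not particular to the C2 start. Gene-dense regions with few expressed genes also lay inside C1 and C2. A candidate explanation, as a hypothesis, is that HZ62 carries copies of the start of A2 in place of this segment: the expressed genes among the first 316 of A2 lay at percentile 95.9 of 4128 overlapping blocks, but only 0.35 above the median block in log2 counts, and the matching of the A2 and C2 starts was assumed. Sequence differences from the reference, errors in its assembly and reads shared between copies were not tested and stay open.

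The seedling libraries differed in their most abundant genes and in genes preferred by seedlings. The median log2 difference of replicate 2 from replicate 1 was 0.12 in 6639 genes preferred by seedlings (by at least 1 on the log2 scale in replicate 1), -0.11 in 6023 genes preferred by flower bud or silique and -0.17 in the 21634 others. Replicate 1 thinned to the depth of replicate 2 gave 2.331% of reads in its 10 most abundant genes, against 4.63% in replicate 2. Random thinning keeps the expected share of each gene, so this outcome was set in advance. It cannot decide whether shallower sequencing was the source of the larger share. The values argue against gene length, taken as the span with introns, as the source of the gap between the gene groups. The length of the transcripts is not known here, so a bias by transcript length was not tested. Seedling-preferred genes exceeded the rest in each of 10 length classes, by at least 0.238. A different make-up, stage or hour of sampling of the seedlings may be involved, which no test here addressed.

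Neighbouring genes shared the tissue in which they were highest more often than shuffled genes, with 1383 adjacent pairs against a mean of 963 (p = 0.001, the smallest that 1000 permutations can give). Overlapping gene models do not account for all of this, since pairs without overlap gave 1.48 times the shuffled mean, nor does read-through from a close neighbour account for all of it, since pairs at least 5 kb apart gave 1.63 times, both above every shuffle. Same-strand pairs gave 1.63 times (95% range 1.496 to 1.78) and opposite-strand pairs 1.33 times (1.21 to 1.46). Each range divides the observed count by the 95% range of shuffled counts, so it covers the spread of the shuffles only. Whether same-strand and opposite-strand ratios differ was therefore not tested. The higher same-strand ratio leaves tandem copies as a candidate explanation for part of the excess over all 3 tissues. By tissue, the same-strand ratio lay inside the opposite-strand range in seedling, which held 853 of the 1383 pairs (1.503 against 1.37, 1.23 to 1.53), and above it in flower bud (1.56 against 1.14, 0.961 to 1.38) and silique (2.52 against 1.51, 1.19 to 2.08). Opposite-strand pairs also exceeded the shuffled mean over all 3 tissues, and sequence similarity was not tested.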
